A study of Mus musculus with 16 samples.

How the data were processed

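RNA was sequenced from endothelial cells of the mouse heart in 16 samples. The cells had been captured with magnetic beads that bind CD31, a surface protein of endothelial cells, from C57BL/6J animals of 8 to 10 weeks, on day 6 after tamoxifen had been given to switch on a Cre recombinase. Each sample pooled cells of 2 mice, per the labels. The 4 groups held 4 samples each: Cre controls, knockouts of Klf2 in endothelial cells (K2KO), knockouts of Klf4 in endothelial cells (K4KO) and knockouts of both (DKO). The genotypes thus form a 2 by 2 factorial. A column kit for RNA extraction and a stranded Illumina library kit are named in the labels' protocols. TopHat, Cuffdiff and the genome build GRCm38 are named in the submitters' processing notes, with neither versions nor roles. The counting tool, the annotation release and whether counting used the strand are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies cannot be told apart.

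The authors deposited 1 table of 43629 genes with Ensembl identifiers, symbols, positions and biotypes, of which 35343 had a read in at least 1 library. Its 16 library columns hold a signal that is never negative: in the deposited values every library's entries were whole multiples of 1 step, so the authors had divided gene read counts by 1 factor per library. That was tested on each column, where 100% of the values came out whole within a tolerance of 0.001 reads. How the factors were estimated is not given in the sources used here. The authors also deposited, for 6 comparisons, a linear fold change as the ratio of group values, and a p-value and an adjusted p-value from a test that the file headers do not name. Those ratios and p-values were used only to count the authors' calls. The control and K4KO columns carry the replicate numbers of the labels. The K2KO and DKO columns are numbered 2 to 5 where the labels start at 1, so they were used as replicates of their group without a link to single samples, and a number after K2KO or DKO is a column number here. No column of values was left unused.

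Dividing each column by its step gave back whole read counts, 21.1 to 106 M reads (megareads) per library. In these libraries 1 read was worth 0.305 to 1.46 scaled counts, so genes with few scaled counts carry a large counting error. The design fixed before the data were examined expected FPKM values, and the values turned out to be scaled counts. The test written for normalised values was therefore kept as the main one: limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with trend) on log2(value + 1), for genes with a value of at least 1 in at least 4 libraries, which left 23816 genes. All 16 libraries entered 1 model with 4 group means and no covariate. P-values were adjusted by the Benjamini-Hochberg method within each of 7 comparisons, and a gene was called when its adjusted p was below 0.05. A log2 change on this scale understates the change of genes with few reads. The interaction was the contrast of the DKO minus K2KO difference with the K4KO minus control difference. For Klf2 and Klf4 a two-sided exact permutation test of 4 against 4 libraries was added.

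A set of 40 gene lists with 832 entries was fixed before the data were examined, covering endothelial functions, pathways known for these factors and markers of other cells that bead isolation from heart could carry over. In the table, 829 entries were matched, 5 of them through another symbol of the same gene, and 42462 of the table's genes carried a current symbol. Lists with at least 5 tested members were tested with camera from limma, with a preset correlation of 0.01 and adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Members called were also counted adjusted over the list alone. Genes named in the text followed a rule fixed before the data were examined. It took Klf2 and Klf4. For DKO against control it took the 10 largest rises and the 10 largest falls among called genes whose 4 libraries all lay beyond all 4 control libraries and whose higher group mean was at least 100. For each single knockout it took 5 and 5 by the same rule, and for each other comparison 4 and 4, without the separation of libraries for the interaction. It left out gene models named Gm with digits or ending in Rik. For each list it took up to 4 members with the smallest p in DKO against control, and not all of these are named in the text. A gene that this rule takes is not reported here.

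Alternatives planned before the data were examined were a pseudocount of 0.1, no filter, a mean of at least 5, quantile normalisation, scaling to the same median, a fit of only the groups compared, robust limma without a trend, library quality weights, a replicate block, a 2-fold threshold and leaving out each library in turn. Alternatives chosen after seeing the data were edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood test) and DESeq2 1.42.0 on the recovered reads, a filter of 10, leaving out the 2 libraries rich in Gm10800, the cardiomyocyte marker level as a covariate, and thinning to the smallest library. For control and K4KO the deviations of same-numbered libraries from their group means correlated at 0.157, 0.213, 0.227 and 0.533 across genes, all above 0.1, so by the rule set for this check the numbers were taken to pair these libraries, and the block was fitted for this comparison. The differently numbered pairs ran from -0.550 to 0.427, the highest being control 2 with K4KO 1, above 3 of the 4 same-numbered values. The pairing rests on the shared numbers in the labels and on this check. Comparisons with the same controls were set beside 50 simulated sets of unchanged groups and the 6 splits of the controls into 2 and 2. No pair of libraries of a group agreed within sampling noise. The labels give no sequencing batch. Labels describe samples as separate pools of mice, and p-values measure the spread between those pools.

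The tests were tried on simulated data for DKO against control, with 23153 genes tested by limma. Of 67, 67 and 66 genes changed by 1.5-fold, 2-fold and 4-fold, 22.4%, 47.8% and 65.2% were recovered. Among those with a mean of at least 100, the recovered numbers were 14 of 24, 29 of 31 and 29 of 29. In the same run 7 unchanged genes were called, and the 1 list moved among 20 was called with no other. In the real comparison 38.3% of the genes tested were called, a far larger share than was changed here. The p-value adjustment depends on that share, so recovery there may differ. Exact intervals for ratios of reads (Clopper-Pearson, 95%) cover counting error only, since PCR copies are not independent molecules. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for preparation and figures. Exon-level reads, which would show a deleted exon directly, were not used here.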

Results

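Gene expression was measured by RNA sequencing in endothelial cells isolated from the mouse heart, 6 days after tamoxifen, in 4 genotypes with 4 samples each. The genotypes were a Cre control and endothelial deletion of Klf2, of Klf4 or of both, which encode Krüppel-like transcription factors that blood flow induces in endothelium. The libraries held 23.5 to 24.3 M reads (megareads) in the control group, 32.4 to 51.0 M in K2KO, 21.1 to 25.4 M in K4KO, and 25.3 to 29.3 M in 3 DKO libraries with 106 M in DKO library 4. Mitochondrial ribosomal RNA made up 16.8 to 22.8% of reads. Mitochondrial protein-coding genes took 0.819 to 0.969% of reads in the DKO libraries and 1.11 to 1.53% in the others, and Malat1, a nuclear RNA, took 0.453 to 0.617% against 0.651 to 1.38%. The first principal component of 12027 genes carried 69.1% of the variance and parted the DKO libraries from the other 12, and the second carried 9.83%. Values below are scaled counts, mean ± SD over n = 4 libraries, and changes are log2 ± SE from limma.

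Klf2 (ENSMUSG00000055148, chromosome 8, 72319033 to 72321656) and Klf4 (ENSMUSG00000003032, chromosome 4, 55527143 to 55532466) were examined first, as a check of the labels. Klf2 fell in K2KO from 7227 ± 2359 to 3354 ± 203, a log2 change of -1.06 ± 0.16 (limma adjusted p = 0.00682, 4 of 4 libraries below every control). With robust limma and no trend its adjusted p was 0.0879, the highest of a range from 1.08e-06 over the alternatives tried. The two-sided exact permutation p was 0.0286, the smallest that 4 against 4 libraries allow. Klf4 in K4KO was 5819 ± 705 against 9691 ± 2466 in controls, with 4 of 4 libraries below every control (exact permutation p = 0.0286). Its log2 change of -0.71 ± 0.15 had an adjusted p of 0.118 in limma, and 0.0284 with same-numbered control and K4KO libraries as a block. In the libraries labelled DKO neither gene was lower: Klf2 stood at 9066 ± 1538 (log2 0.36 ± 0.16, adjusted p = 0.0881, exact permutation p = 0.2) and Klf4 at 9447 ± 1898 (log2 -0.03 ± 0.15, adjusted p = 0.923, exact permutation p = 0.943). Scaling the libraries to the same median turned the sign of that Klf4 value, to 0.24, and took the Klf2 value past the threshold, to 0.63 with an adjusted p of 0.00676. Against K2KO, Klf2 was higher in the DKO-labelled libraries by 1.42 ± 0.16 (adjusted p = 1.19e-06, 4 of 4 libraries), and against K4KO, Klf4 was higher by 0.69 ± 0.15 (adjusted p = 0.00102). Reads were counted over whole genes, so a deleted exon is not visible here, and the group is called DKO-labelled below because the check did not show a loss of either transcript.

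**Figure D1:**
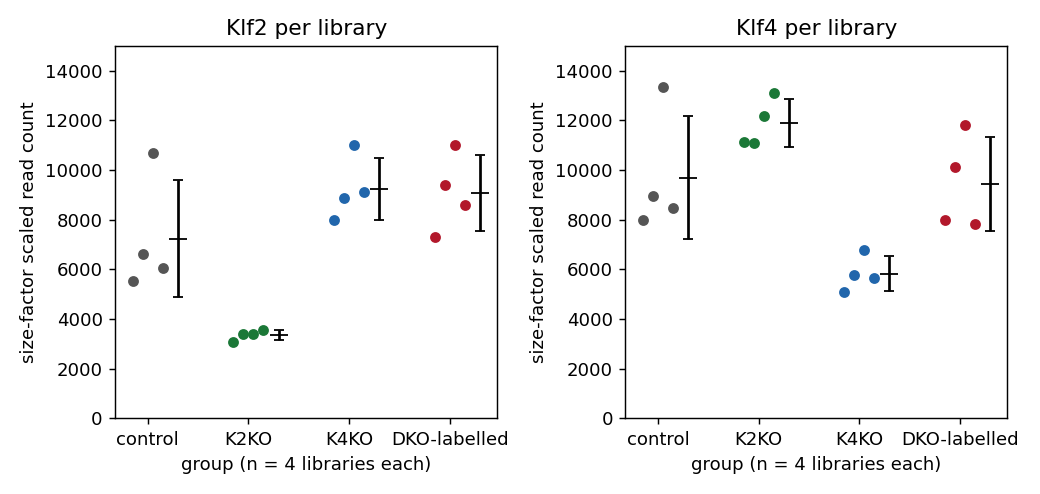
Size-factor scaled read counts of Klf2 (left) and Klf4 (right) in each of the 16 libraries by group, with bars at the group mean ± SD (n = 4). Klf2 is low in K2KO at 3354 and Klf4 in K4KO at 5819, while the DKO-labelled libraries average 9066 and 9447.

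The comparison of the DKO-labelled libraries with controls asks what changed in cardiac endothelium meant to lack both factors, with the caveat that neither transcript was lower there. Among the largest rises was Tnc, encoding the matrix glycoprotein tenascin-C, which went from 299 ± 45 to 11078 ± 1482 (log2 5.21 ± 0.12, adjusted p = 7.55e-16). Pgf, a growth factor of the VEGF family, rose from 502 ± 67.3 to 8656 ± 3832 (4.00 ± 0.23), and Inhbb, a subunit of activin B, rose from 93.7 ± 18.9 to 2278 ± 936 (4.50 ± 0.26). Sh2d5 (6.06 ± 0.52), the costimulatory receptor gene Tnfrsf9 (5.37 ± 0.36), the growth-cone gene Gap43 (5.35 ± 0.37), Disp2 (5.32 ± 0.41) and Ptchd1 (4.10 ± 0.17) also rose. Clic6 (6.05 ± 0.59) and the arginase gene Arg1 (5.21 ± 0.65) rose from very few reads. For Clic6 there were 4 reads over the control libraries and 1258 over the DKO-labelled ones, a scaled ratio of 160 (exact 95% interval 62.2 to 587), and for Arg1 there were 8 control reads, a ratio of 43.2 (21.8 to 100).

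The largest falls included Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, from 394 ± 140 to 5.34 ± 4.7 (-6.14 ± 0.40, adjusted p = 1.91e-09). Slc26a10 fell from 6451 ± 1549 to 301 ± 287 (-5.09 ± 0.56), Cytl1, a secreted protein gene, from 1384 ± 376 to 91.6 ± 89.5 (-4.34 ± 0.41), and Pltp, which encodes phospholipid transfer protein, from 2290 ± 466 to 228 ± 127 (-3.43 ± 0.25). The carboxylesterase gene Ces2e (-4.25), Prrt4 (-4.11), the tyrosine phosphatase gene Ptprr (-4.07), the transcription factor gene Tcf23 (-4.07), the Wnt ligand gene Wnt9b (-3.55) and the mitochondrial uncoupling protein gene Ucp3 (-3.41) fell as well. For each of these 20 genes all 4 DKO-labelled libraries lay beyond all 4 controls, as the naming rule required. None of the 20 was called in either single knockout without a block. With same-numbered control and K4KO libraries as a block, Wnt9b (-1.46, adjusted p = 0.0253) and Tcf23 (-1.17, adjusted p = 0.0278) were called lower in K4KO.

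Cell cycle genes formed the list with the smallest p. Of 40 measured members 39 rose and 0 fell (40 and 0 adjusted over the list alone), with a median log2 change of 2.38. The mitotic kinase gene Cdk1 rose from 224 ± 164 to 2035 ± 409 (3.42), Ube2c, of the anaphase-promoting complex, by 3.46, its activator Cdc20 by 2.04 and the thymidylate synthase gene Tyms by 1.67. In the tip cell and sprouting list, genes of endothelial cells that lead new vessels, 21 of 26 rose and 3 fell (21 and 3 adjusted over the list alone, median 1.29). Apln, encoding the peptide apelin, rose from 2047 ± 655 to 15760 ± 1317 (2.99), Angpt2, the angiopoietin that destabilises vessels, from 576 ± 75.3 to 2557 ± 188 (2.15), and the basement membrane gene Nid1 by 1.48. In the mesenchymal transition and matrix list 20 of 29 rose and 3 fell (21 and 4 adjusted over the list alone, median 0.87). These included the membrane collagenase gene Mmp14, from 658 ± 17.3 to 6694 ± 1659 (3.31), the intermediate filament gene Vim (2.07), the collagen-binding gene Sparc (1.93) and the lysyl oxidase gene Loxl2 (2.46). Camera gave adjusted p values of 1.22e-23, 5.00e-11 and 4.08e-09 for these lists. Each had an adjusted p = 0.349 with an estimated correlation, so none of the 3 calls held there.

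Adhesion and chemokine genes rose in 20 of 31 cases and fell in 4 (20 and 4 adjusted over the list alone, median 0.74, camera adjusted p = 0.000531, and adjusted p = 0.399 with an estimated correlation). Sele, the leukocyte adhesion receptor E-selectin, rose from 1200 ± 364 to 5584 ± 264 (2.27), the monocyte chemokine gene Ccl2 by 2.38 and the cytokine gene Il1a by 2.94, while Cxcl12, a chemokine that retains leukocytes, fell by 1.25. Glycolysis genes rose in 11 of 19 cases and fell in 4 (13 and 4 adjusted over the list alone, median 0.78, camera adjusted p = 0.0038, and adjusted p = 0.493 with an estimated correlation), with Pgk1 at 2.10, Pkm at 1.38, Pfkp at 1.25 and the glucose transporter gene Slc2a1 at 1.78. In the hypoxia list, 9 of 19 rose and 4 fell (10 and 4 adjusted over the list alone, camera adjusted p = 0.0219, and adjusted p = 0.493 with an estimated correlation), among them Egln3 (2.19) and Ero1l (1.04), both targets of hypoxia-inducible factors, and Hif1a (1.12), which encodes one. In the unfolded protein response list 9 of 17 rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 0.00167, and adjusted p = 0.479 with an estimated correlation), with the chaperone gene Hspa5 at 1.05, its regulator Xbp1 at 0.87 and the asparagine synthetase gene Asns at 1.19. Antioxidant genes rose in 10 of 18 cases and fell in 3 (10 and 3 adjusted over the list alone, camera adjusted p = 0.0133, and adjusted p = 0.410 with an estimated correlation), with Txn1 at 1.09, Txnrd1 at 0.95 and Gstm1 at -1.12.

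Of 27 Notch and arterial genes 12 fell and 4 rose (13 and 5 adjusted over the list alone, camera adjusted p = 0.0209, and adjusted p = 0.493 with an estimated correlation), with the Notch ligand gene Dll1 at -1.77, the elastic fibre gene Fbln5 at -1.70 and the kinase gene Bmx at -1.28. With libraries scaled to the same median 9 rose and 9 fell, and their median of -0.24 turned to 0.02. Interferon response genes fell in 14 of 34 cases and rose in 1 (14 and 1 adjusted over the list alone, camera adjusted p = 0.0278, and adjusted p = 0.766 with an estimated correlation), with Gbp4 at -1.95 and Oas2 at -1.34. The member that rose was Mx1, at 1.35. As mean log2, the interferon level of DKO library 2 was 11.31, above the controls (11.12 to 11.19), and the other DKO-labelled libraries lay at 10.70 to 10.86. With that scaling 8 interferon genes rose and 5 fell and their median of -0.24 turned to 0.03. Immediate early genes, which tissue dissociation induces, fell in 14 of 26 cases and rose in 4 (16 and 4 adjusted over the list alone, camera adjusted p = 0.0245, and adjusted p = 0.766 with an estimated correlation). Ier5 (-0.68) and Jun (-0.67) fell, and Myc (2.28) and Maff (1.18) rose, while 4 rose and 4 fell with that scaling. Mitochondrially encoded genes fell in 5 of 9 cases (7 adjusted over the list alone, camera adjusted p = 0.00954, and adjusted p = 0.578 with an estimated correlation), with mt-Nd2 at -0.76, and in 2 with that scaling. With quantile normalisation the numbers higher and lower were 2 and 14 for the Notch list and 1 and 17 for the interferon list. For the immediate early list they were 3 and 17, and for the mitochondrially encoded list 0 and 6. edgeR on the recovered reads gave 4 and 13, 1 and 15, 3 and 16, and 0 and 7 for these lists in that order. Each list median stayed negative with both of these settings.

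Genes already tied to Klf2 or Klf4 in endothelium moved both ways: of 29, 8 rose and 11 fell (10 and 12 adjusted over the list alone, camera adjusted p = 0.505). Thbd, encoding the anticoagulant receptor thrombomodulin, fell from 21015 ± 3023 to 5298 ± 1312 (-2.01), and the cell cycle inhibitor gene Cdkn1c from 2193 ± 459 to 478 ± 112 (-2.20). In the coagulation and fibrinolysis list 14 of 32 rose and 8 fell (14 and 8 adjusted over the list alone, camera adjusted p = 0.0623). There the urokinase gene Plau (2.26) and the protein C receptor gene Procr (1.70) rose and the nucleotidase gene Entpd1 (-1.62) fell. Vasomotor genes rose in 9 of 30 cases and fell in 10 (9 and 12 adjusted over the list alone, camera adjusted p = 0.978), among them Gucy1a3, a subunit of the nitric oxide receptor, at -1.25, Ddah1, which degrades an inhibitor of nitric oxide synthase, at 1.19 and the potassium channel gene Kcnn3 at -1.91. Of 35 junction and permeability genes 13 rose and 8 fell (14 and 9 adjusted over the list alone, camera adjusted p = 0.459), with the junctional adhesion gene Jam2 down from 24207 ± 1509 to 5705 ± 1762 (-2.13) and the nectin gene Pvrl2 up by 1.89. Endothelial identity genes rose in 12 of 34 cases and fell in 11 (13 and 13 adjusted over the list alone, camera adjusted p = 0.835). Cd93 (1.37) and Ecscr (0.88) rose, and Podxl (-1.52) and the angiopoietin receptor gene Tek (-0.99) fell. Other Krüppel-like factor genes changed too, with Klf6 up by 1.44, and Klf3 (-0.76), Klf9 (-1.01) and Klf12 (-0.77) down. The medians of the known target, vasomotor, junction, identity and Krüppel-like lists lay near 0 and changed sign with at least 1 of the settings tried. Scaled to the same median, the numbers higher and lower were 18 and 4 for the identity list (7 and 14 with quantile normalisation), 10 and 9 for the known targets, 10 and 5 for the vasomotor, 15 and 6 for the junction, 17 and 5 for the coagulation and 4 and 4 for the Krüppel-like list.

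**Figure D2:**
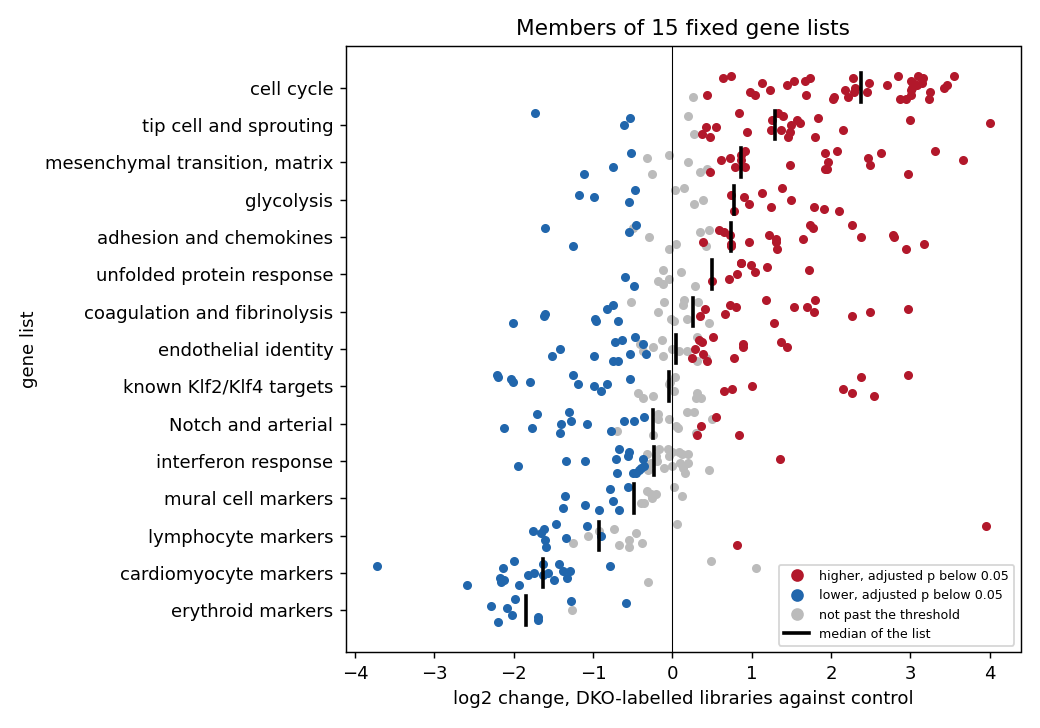
Log2 change of each member of 15 gene lists between the DKO-labelled and control libraries (x axis), with members called higher in red, called lower in blue and not called in grey, and a black bar at the list median. Cell cycle genes lie to the right, with a median of 2.38, and cardiomyocyte markers to the left, with a median of -1.63.

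Markers of other cells were also measured, because bead isolation can carry over RNA of neighbouring cells. Cardiomyocyte markers fell in 19 of 22 cases (19 fell and 1 rose adjusted over the list alone, median -1.63, camera adjusted p = 5.00e-11, and adjusted p = 0.349 with an estimated correlation). The myosin gene Myh6 went from 42741 ± 13253 to 7097 ± 2023 (-2.59) and Myl2 from 4598 ± 748 to 1485 ± 280 (-1.63). Erythroid genes fell in 9 of 10 cases (10 adjusted over the list alone, median -1.84, camera adjusted p = 7.46e-06), lymphocyte genes in 9 of 21 with 2 rising (9 and 2 adjusted over the list alone, camera adjusted p = 0.00112), both with an adjusted p = 0.399 with an estimated correlation. Here Hbb-bs, a beta globin, fell from 15647 ± 2242 to 3902 ± 844 and Ighm, an immunoglobulin chain, from 724 ± 88.2 to 236 ± 21.3. Mural cell genes fell in 8 of 16 cases (8 adjusted over the list alone, median -0.48, camera adjusted p = 0.000613, and adjusted p = 0.493 with an estimated correlation), with the smooth muscle myosin gene Myh11 at -1.38. Fibroblast genes were mixed, 6 up and 3 down of 16 (8 and 4 adjusted over the list alone, camera adjusted p = 0.794), with Pi16 at -1.80 and the collagen gene Col1a2 at 0.79. Macrophage genes had 2 rises and 2 falls among 20 (1 and 2 adjusted over the list alone, camera adjusted p = 0.978), and 5 and 1 with libraries scaled to the same median. The cardiomyocyte, erythroid and mural levels thus differ between the same libraries as the lists called above. With the cardiomyocyte level of each library as a covariate, an alternative chosen after seeing the data, the cell cycle median was 2.99 with 32 members called. The tip cell list had 14 calls in place of 24 and a median of 1.19, and the matrix list 17 in place of 23 with its median up from 0.87 to 1.75. The erythroid list went from 9 calls to 0 with that covariate, its median moving from -1.84 to -1.03 as the median SE rose from 0.245 to 0.614.

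**Figure D3:**
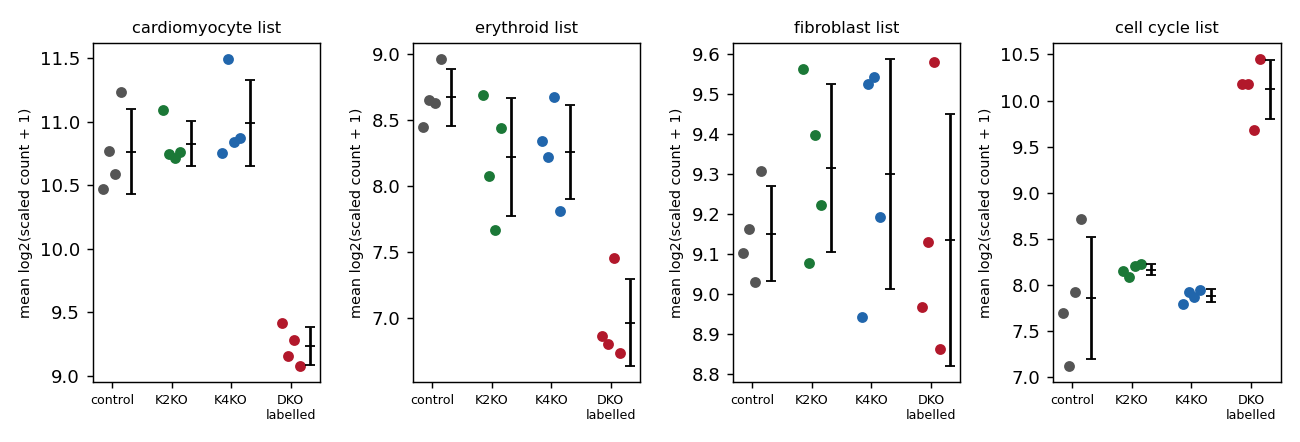
Mean log2(scaled count + 1) of the cardiomyocyte, erythroid, fibroblast and cell cycle lists in each of the 16 libraries by group, with bars at the group mean ± SD (n = 4). In the DKO-labelled libraries the cardiomyocyte and erythroid levels are lower and the cell cycle level higher than in the other groups.

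In total limma called 9119 of 23816 genes between the DKO-labelled and control libraries, 4528 higher and 4591 lower, of which 3488 changed at least 2-fold. Scaling the libraries to the same median moved the median log2 change of all genes from -0.03 to 0.18 and the share of calls that were higher from 49.7% to 70.4%, so the balance of rises and falls depends on the scaling. With the cardiomyocyte covariate 1263 genes were called, 1232 of them among the 9119, with the median SE up from 0.233 to 0.586, since its level separates the DKO-labelled libraries from the rest. Of the 20 genes of large change named first, Sh2d5 (1.91), Arg1 (5.85), Prrt4 (-4.47), Wnt9b (-4.21) and Ucp3 (-1.89) lost their calls with it, at adjusted p values of 0.216, 0.0545, 0.0851, 0.0675 and 0.212. The authors' deposited table calls 6094 genes here, of which 6090 were also called by limma, in the same direction.

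The K2KO comparison asks what loss of Klf2 alone changed, and 40 genes were called, 33 higher and 7 lower. Calr3, a calreticulin gene on chromosome 8, rose from 14.8 ± 2.16 to 132 ± 13.8 (3.08 ± 0.25, adjusted p = 4.19e-06). The aggrecan-cleaving protease gene Adamts4 rose from 609 ± 375 to 1947 ± 292 (1.83 ± 0.30, adjusted p = 0.0113), the sulfatase gene Arsi by 1.19, the integrin ligand gene Npnt by 1.17 and Trim69 by 1.11. Mri1, of the methionine salvage pathway, fell from 235 ± 16.2 to 97.0 ± 13.6 (-1.28 ± 0.16, adjusted p = 0.000905), and the alarmin cytokine gene Il33 (-0.85), the lysosomal mannosidase gene Man2b1 (-0.70) and the T cell costimulatory ligand gene Icosl (-0.56) fell along with Klf2. For each of these genes 4 of 4 libraries lay beyond every control, as the naming rule required. With 1 library left out in turn, the call of Il33 was lost in 7 of 8 fits, all but that without control 3 (adjusted p up to 0.199). That of Icosl was lost in 5, without control 1 or 2 or K2KO library 2, 3 or 5 (up to 0.0906). Adamts4 was lost without control 1 or 2 or K2KO library 2 or 4 (up to 0.0673). Npnt was lost without control 2 or K2KO library 4 or 5 (up to 0.0594). Calr3, Arsi, Trim69, Mri1, Man2b1 and Klf2 kept their calls in 8 of 8 fits.

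Adhesion and chemokine genes held 4 rises and 1 fall in K2KO among 31 (13 and 1 adjusted over the list alone, median 0.22, camera adjusted p = 3.25e-09, and adjusted p = 0.201 with an estimated correlation). Sele was called at 0.86, and Selp, encoding P-selectin (0.97, adjusted p = 0.00592), and Icam1, a leukocyte adhesion receptor gene (0.94, adjusted p = 0.0194), were named after their values were seen. With 1 library left out Selp kept its call in 8 of 8 fits. Sele lost it without control 1 or K2KO library 2 or 4 (adjusted p up to 0.0818), and Icam1 in 7 of 8 fits, all but that without control 3 (up to 0.104). In the NF-kB list 2 of 18 rose (7 adjusted over the list alone, median 0.21, camera adjusted p = 2.57e-09) and in the unfolded protein response list 0 of 17 (8 adjusted over the list alone, median 0.31, camera adjusted p = 4.15e-08). Both lists also had an adjusted p = 0.201 with an estimated correlation. Immediate early genes had a median of 0.42 with 0 called (14 higher adjusted over the list alone, camera adjusted p = 1.67e-13, and adjusted p = 0.311 with an estimated correlation). Control 3 stood at K2KO levels in these lists. As mean log2 its immediate early level was 12.80 (other controls 11.91 to 12.06, K2KO 12.56 to 12.75). Its NF-kB level was 10.25 (9.87 to 9.92, K2KO 10.23 to 10.40) and its unfolded protein response level 10.71 (10.38 to 10.57, K2KO 10.70 to 10.86). These rises thus do not part K2KO from every control, and their cause was not tested. Erythroid markers had a median of -0.45 (camera adjusted p = 2.98e-06, and adjusted p = 0.311 with an estimated correlation) and macrophage markers of -0.32 (camera adjusted p = 7.06e-06, and adjusted p = 0.553 with an estimated correlation), and these moved beside the gene groups above. Camera with its preset correlation also called the cell cycle (median 0.32), tip cell (0.16), matrix (0.16), arrest and apoptosis (0.15), ADAMTS (0.23) and lymphocyte (-0.15) lists, 12 in all. Their adjusted p values ran from 0.201 to 0.854 with an estimated correlation, so 0 were called, and fry called 0.

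The count of 40 rests on few libraries. It was 16, 18, 137 and 25 without control 1, 2, 3 and 4, and 13, 20, 18 and 17 without K2KO library 2, 3, 4 and 5, and edgeR called 43 genes and DESeq2 123. Control 3 held 1166 scaled counts of Adamts4, and without it that gene's change was 2.20. The authors' deposited table calls 45 genes in this comparison, 31 of them called here.

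The K4KO comparison asks what loss of Klf4 alone changed, and 15 genes were called, 7 higher and 8 lower. Ankrd6, encoding the Wnt pathway protein Diversin, rose from 109 ± 18.8 to 295 ± 15.4 (1.45 ± 0.14, adjusted p = 9.82e-05), and Alad, a gene of haem synthesis, from 304 ± 37.4 to 633 ± 136 (1.04 ± 0.18, adjusted p = 0.0379), and both lie on chromosome 4, as Klf4 does. Pi16, a fibroblast marker, fell from 694 ± 182 to 331 ± 49.2 (-1.04 ± 0.17, adjusted p = 0.0267), Ramp3, a coreceptor of adrenomedullin, from 747 ± 190 to 378 ± 84.3 (-0.97), and the collagen gene Col8a1 (-0.58) and Ankrd33b (-0.67) fell. Tusc1 (0.99), Tmem56 (0.88), Sele (0.80) and Rtn1 (-0.82) were also called, but not with same-numbered libraries as a block, where their adjusted p values were 0.182, 0.146, 0.137 and 0.206. For each gene named, 4 of 4 libraries lay beyond every control, as the naming rule required. With 1 library left out in turn Ankrd6 and Col8a1 kept their calls in 8 of 8 fits. Alad was called in 1 of 8, without K4KO 4 (adjusted p up to 0.167). Ramp3 was called in 2, without control 4 or K4KO 1 (up to 0.198), and Pi16 in 3, without control 3 or 4 or K4KO 2 (up to 0.109). Ankrd33b was called in 4, without control 3 or 4 or K4KO 1 or 4 (up to 0.108). Tusc1, Tmem56, Sele and Rtn1 were called in 1 each, without K4KO 1, K4KO 2, control 3 and K4KO 1.

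Macrophage markers had a median of -0.40 in K4KO with 0 of 20 called (0 adjusted over the list alone, camera adjusted p = 2.53e-06), erythroid markers of -0.42 with 0 of 10 called (0 adjusted over the list alone, camera adjusted p = 0.000182), and the tip cell list of -0.13 with 1 of 26 lower (4 adjusted over the list alone, camera adjusted p = 0.000147). Each had an adjusted p = 0.574 with an estimated correlation. Cardiomyocyte markers had a median of 0.22 (camera adjusted p = 0.0137, and adjusted p = 0.672 with an estimated correlation). Camera also called the endothelial identity (median -0.08), cardiac capillary (-0.11), Notch and arterial (-0.10), BMP and TGF-beta (-0.11), guidance (-0.07), neutrophil (-0.53), matrix (0.15) and mural (0.13) lists, 12 in all and 18 with the block. Their adjusted p values ran from 0.574 to 0.672 with an estimated correlation, so 0 were called, and fry called 0. The block calls that the fit without it lacked were hypoxia (adjusted p = 0.0312), known targets (0.0284), fibroblast (0.0213), Schwann cell (0.0284), mitochondrially encoded (0.0213) and vasomotor genes (0.0213). With the block 14 genes were called, 3 higher and 11 lower, 8 of them among the 15. The 6 gained were Klf4, Wnt9b (-1.46), Tcf23 (-1.17) and, named after their values were seen, Ret (-1.09), Stmn2 (-0.99) and Trpv4 (-0.75), with 4 of 4 libraries below every control except for Trpv4, with 1. Scaling to the same median moved the share of higher calls from 46.7% to 21.4%, and it was 40% with quantile normalisation, 41.2% with edgeR and 30% with DESeq2. The count was 4, 4 and 9 without control 1, 2 and 3, and 8 and 6 without K4KO 2 and 3, while DESeq2 called 80 genes. The authors' deposited table calls 30 genes, 13 of them called here.

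The interaction asks whether the DKO-labelled libraries differ from the sum of the single changes, bearing in mind that neither transcript was lower in them. Tnc exceeded the sum by 5.02 ± 0.17 (adjusted p = 8.2e-13), Clic6 by 6.79 ± 0.83, Disp2 by 4.60 ± 0.58 and Arg1 by 4.71 ± 0.92. Myl7, an atrial myosin light chain (-4.91 ± 0.90), Slc26a10 (-4.11 ± 0.80), Cytl1 (-3.83 ± 0.58) and the neural splicing factor gene Srrm4 (-3.80 ± 0.49) lay below it. In the cell cycle list 39 of 40 had a positive interaction and 0 a negative one (39 and 0 adjusted over the list alone, median 2.06, camera adjusted p = 8.81e-23, and adjusted p = 0.463 with an estimated correlation). In the cardiomyocyte list 18 of 22 had a negative one (19 adjusted over the list alone, median -1.77, camera adjusted p = 4.21e-13, and adjusted p = 0.410 with an estimated correlation). Klf2 itself had an interaction of 1.03 (adjusted p = 0.00237). In all 6352 genes were called, 3060 above the sum and 3292 below. Of the 9119 genes called between the DKO-labelled and control libraries 5420 also had a called interaction, 5412 with the same sign. The interaction contains the difference between the DKO-labelled and control libraries for which these genes were chosen, so agreement in sign was likely in advance. Scaling to the same median moved the share of calls above the sum from 48.2% to 73.4%. That share was 49.8% with quantile normalisation, 48.2% with edgeR and 50.6% with DESeq2. With the cardiomyocyte covariate 172 genes were called, 168 of them among the 6352. Of the genes named here Tnc kept its call with it (5.14). Clic6 (7.50), Disp2 (5.29), Arg1 (5.47), Slc26a10 (-4.585) and Cytl1 (-3.87) lost theirs although their values were no smaller. Myl7 (-1.84), Srrm4 (-0.69) and Klf2 (0.61) lost theirs with smaller values.

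**Figure D4:**
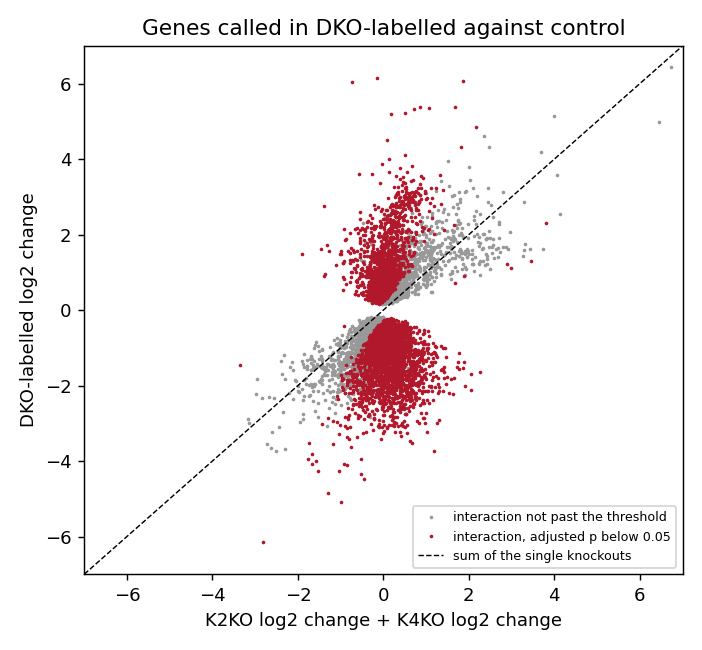
Log2 change in the DKO-labelled libraries (y axis) against the sum of the K2KO and K4KO log2 changes (x axis) for the 9119 genes called between the DKO-labelled and control libraries, with genes whose interaction was called in red and a dashed line where both are equal. The genes shown were chosen for their change on the y axis, and 5420 of them are red.

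The DKO-labelled libraries were also set against each single knockout, which asks what loss of the other factor adds. Against K2KO, Tnc (5.03), Disp2 (5.71), Arg1 (5.07) and Clic6 (6.67) were higher and Cyp1a1 (-5.09), Slc26a10 (-4.68), Cytl1 (-4.004) and Ptprr (-3.99) lower. For these genes all 4 libraries lay beyond all 4 K2KO libraries, as the naming rule required. Clic6 had 2 reads over the K2KO libraries, a scaled ratio of 542 (exact 95% interval 150 to 4480). Against K4KO, Tnc (5.20), Sh2d5 (5.58), Tnfrsf9 (4.92) and Clic6 (6.16) were higher and Myl7 (-4.84), Slc26a10 (-4.51), Cyp1a1 (-4.37) and Cytl1 (-4.16) lower. Cell cycle genes were higher in 39 of 40 cases in both comparisons (39 adjusted over the list alone, medians 2.11 and 2.38, camera adjusted p = 5.78e-23 and 2.48e-24), with an adjusted p = 0.377 and an adjusted p = 0.360 with an estimated correlation. Immediate early genes fell against K2KO in 21 of 26 cases and rose in 2 (21 and 2 adjusted over the list alone, median -1.05, camera adjusted p = 8.82e-06, and adjusted p = 0.606 with an estimated correlation). Limma called 8717 genes against K2KO (4210 higher, 4507 lower) and 9420 against K4KO (4557 higher, 4863 lower). The higher share moved from 48.3% to 70.2% and from 48.4% to 70.9% with scaling to the same median. It was 49.9% and 50.2% with quantile normalisation, 47.9% and 47.5% with edgeR, and 49.8% and 48.8% with DESeq2. With the cardiomyocyte covariate 838 and 602 genes were called, 817 and 592 of them also called without it. With that covariate Arg1 (5.73), Cyp1a1 (-3.485), Slc26a10 (-5.10), Cytl1 (-4.04), Ptprr (-3.96) and Klf2 (1.06) lost their calls against K2KO. Against K4KO, Sh2d5 (0.81), Myl7 (-1.86), Slc26a10 (-4.98), Cyp1a1 (-2.61), Cytl1 (-4.205) and Klf4 (0.47) lost theirs. The values of Arg1, Slc26a10, Cytl1 and Ptprr were thus about as large as without it or larger, and the others were smaller. The authors' deposited table calls 5978 and 5893 genes, of which 5936 and 5892 were called here.

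K2KO and K4KO were compared directly to ask where the single knockouts differ. Calr3 was higher in K2KO by 2.36 ± 0.25 (adjusted p = 0.000143), the histamine receptor gene Hrh2 by 1.77 ± 0.19 with 348 ± 34.3 against 104 ± 27.2, the red cell adhesion gene Icam4 by 1.51 and the immune checkpoint gene Lag3 by 1.48. Ankrd6 (-1.47), Alad (-1.26) and Mri1 (-1.11) were lower in K2KO, as was Klf2 (-1.45), while Klf4 was higher by 1.03 (adjusted p = 0.00207). Tip cell genes had a median of 0.29 with 2 of 26 higher (11 adjusted over the list alone, camera adjusted p = 1.69e-13, and adjusted p = 0.157 with an estimated correlation). Of 106 genes called, 83 were higher and 23 lower in K2KO, and camera called 23 lists with its preset and 0 with an estimated correlation. The count was 60, 54, 60 and 54 without K2KO library 2, 3, 4 and 5, and 70, 61 and 211 without K4KO 1, 2 and 4. The authors' deposited table calls 66 genes, 55 of them called here.

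All single and double comparisons share the 4 control libraries, so overlaps of their calls lie above chance by construction. Sele was the 1 gene called in both single knockouts, higher in each but not called in K4KO with the block, where independent lists would share 0.0097. Simulated unchanged groups shared 0, but almost no gene is called in them, so that value was fixed in advance. Of the 40 K2KO genes, 21 were called higher and 6 lower in the DKO-labelled libraries as well and 5 were called in the opposite direction, against 6.27 and 1.35 for independent lists. For Icam1, which was named after its values were seen, the DKO-labelled change was -0.54 (adjusted p = 0.0133) against 0.94 in K2KO. Of the 15 K4KO genes, 3 were called higher and 8 lower in the DKO-labelled libraries, against 1.33 and 1.54. With the controls split into 2 and 2 these overlaps averaged 0 for the single knockouts over the 6 splits. They averaged 17.8 and 3.33 for K2KO, against 5.09 and 0.776 for independent lists, and 1.5 and 1.83 for K4KO, against 0.653 and 0.335. For K2KO they ran from 4 to 69 higher and 2 to 8 lower, with 0 to 20 in opposite directions, and for K4KO from 0 to 7 higher and 0 to 9 lower. Across genes, which are not independent replicates, the covariance of the log2 changes was 0.105 for K2KO and K4KO (simulated 0.0704, correlation 0.608 against 0.502), 0.102 for K2KO and DKO (simulated 0.0700, correlation 0.309 against 0.499) and 0.0724 for K4KO and DKO (simulated 0.0699, correlation 0.196 against 0.499). With split controls the covariances were 0.0364, 0.0339 and 0.004.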

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

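The tests on the Klf2 and Klf4 reads, on chromosomal position and on the macrophage quartile were chosen only after the result was seen, while the slope tests on the cardiomyocyte level and the counts of other splits were written before.

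Reads of Klf2 and Klf4 were not lower in the DKO-labelled libraries although 9119 genes differed there. A swap among the 16 libraries is argued against, since 0 of the 12 other libraries had both genes below the lowest control. Partial recombination could lie behind it and stays open: over the 39 other genes called in K2KO, the median ratio of the DKO-labelled to the K2KO log2 change was 0.863 (quartiles 0.221 to 1.46, 19 genes above 1, 0.828 to 0.993 with 1 library left out), which decides neither way. Reads from a recombined allele, or raised transcription of the locus, may also give this, as Klf2 was 1.42 higher on the log2 scale than in K2KO, and whole-gene reads cannot separate these. A biological difference between the double and single knockouts stays open and untested.

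Genes called in the single knockouts lay on the chromosome of the deleted gene: 5 of 39 K2KO genes other than Klf2 on chromosome 8 (1.89 by chance, one-sided Fisher's exact p = 0.0393) and 5 of 15 K4KO genes on chromosome 4 (0.986 by chance, p = 0.0021). Chance placement stays open for chromosome 8. Chromosome 18, with no targeted gene, held 5 K2KO calls, Arsi among them, against 0.987 by chance (one-sided Fisher's exact p = 0.00289). The cause of that excess was not tested, and the count does not use distances between genes, so it decides neither way. For chromosome 4 chance placement stays open as well. With same-numbered libraries as a block 3 of 13 calls other than Klf4 lay there (0.854 by chance, one-sided Fisher's exact p = 0.0493). With 1 library left out the p of that test ran from 9.16e-05 to 0.114, at 0.114 without control 3, 0.0598 without control 4 and 0.0542 without K4KO 3. A local effect of the deletion is argued against for 8 of the 10 genes, which lay farther than 1 Mb away, up to 12.8 Mb on chromosome 8 (Man2b1) and, for a gene also called with the block, 22.7 Mb on chromosome 4 (Ankrd6), and stays open for the 2 within 1 Mb, Fam32a at 0.0993 Mb and Calr3 at 0.105 Mb. Strain variation carried along with the floxed Klf2 allele may explain its side, where 4 of 5 changes were repeated in the DKO-labelled libraries against 23 of 34 elsewhere (one-sided Fisher's exact p = 0.506). Even 5 of 5 would not have brought that p below 0.05, so the test could not separate the explanations. The change not repeated was that of Mast1, which has few reads (4.562 in controls, 35.03 in K2KO and 4.776 in the DKO-labelled libraries). On the Klf4 side 2 of 5 were repeated against 9 of 10 elsewhere, while 38.3% of all genes tested were called in the DKO-labelled libraries. Variation shared by both lines is argued against for Ankrd6 (109 in controls, 295 in K4KO and 103 in the DKO-labelled libraries), AI464131 (59.35, 155.6 and 46.24) and Alad (303.8, 632.5 and 336.7). For these genes variation in the K4KO line alone stays open, and the copy number of Alad differs between inbred strains. Shared variation stays open for Tusc1 (62.74, 127.9 and 89.06) and for Ccl27a, which has few reads (25.99, 3.347 and 1.162). Mast1, AI464131 and Ccl27a were named after their values were seen.

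Cardiomyocyte markers were lower in the DKO-labelled libraries, with Ttn at 49290 against 230700 scaled counts in controls and Myh6 at 7097 against 42741. An equal fall of every other cell type is argued against, since the lower quartile of the macrophage marker changes, -0.271, lay above the upper quartile of the cardiomyocyte changes, -1.346. Fewer cells of several other types stays open. List medians were also negative for erythroid (-1.84), Schwann cell (-1.23), lymphocyte (-0.93), mesothelial (-0.85), adipocyte (-0.59), neutrophil (-0.53), mural (-0.48) and platelet (-0.35) markers. They were near 0 for macrophage (0.03) and fibroblast (0.11) markers. Less cardiomyocyte RNA as the whole cause of the called changes is argued against as well, if slopes on the cardiomyocyte level within the other 3 groups hold at the lower DKO-labelled level. Those slopes predicted a share of 0.0963 of the changes (-0.00992 to 0.207 with 1 library left out). For the cell cycle median the share was -0.368 (-0.74 to 0.072). For the cardiomyocyte median it was 0.881, but the level is the mean of those same marker genes, so a high share was fixed in advance. The signs that the slopes predicted were right for 53.4% of called genes (42.4 to 66.3% with 1 library left out). Whether they hold outside the levels they were fitted on was not tested. A lower carry-over of cardiomyocyte RNA could still account for the cardiomyocyte genes, and a change in the hearts of these mice stays open and untested. With the cardiomyocyte level as a covariate 1263 genes were called, 1232 of them among the 9119, but that level does not overlap between the DKO-labelled and other libraries (9.07 to 9.41 against 10.5 to 11.5).

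Genes called were also counted for other splits of the same libraries, to ask whether a chance split calls as many. For the DKO-labelled libraries against control, 1 of 35 splits, the real one, called as many as 9119 genes, and the highest other called 0. The real split was likewise the only 1 of 35 as large for K2KO (40 genes, highest other 1), DKO against K2KO (8717, highest other 0), DKO against K4KO (9420, highest other 3) and K2KO against K4KO (106, highest other 15). That share is the smallest that 4 against 4 libraries allow, so chance is made unlikely in each comparison but not excluded. A split that mixes DKO-labelled with other libraries also puts their difference into the spread, so few calls were likely there in any case. For the interaction 1 of 100 splits was as large (6352, highest other 5875). That other split was the 1 draw with all 4 DKO-labelled libraries in 1 group, the next called 1222 genes with 3 of them together, and the rest called at most 1, so the count follows how these libraries are grouped, a structure of the samples. For K4KO 2 of 35 splits called as many as 15 genes, the other calling 33 after exchanging control 4 with K4KO 1, so chance is not excluded. Among the 8 splits that part all 4 same-numbered pairs, as the real one does, the real split called 15 and the highest other 1.

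Of 240 group values tested for 1 library standing apart from the other 3, 14 did, where chance gives about 1 in 20, or 12. DKO library 4 held 106 M reads against 25.3 to 29.3 M. K4KO 1 had reads in about 29600 genes against about 21150 to 21580. Gm10800, a gene model of repeated sequence, took 4.13% of reads in K2KO library 2 (others at most 0.0191%) and 7.01% in K4KO 1 (others at most 0.0697%). Single genes stood apart for Arg1 in K4KO 4 (7.60 scaled counts against 1.34 to 2.38), Pltp in DKO library 2 (417.9 against 161.8 to 169.2), Adamts4 in control 3 (1166 against 367.3 to 495.6), Arsi in DKO library 4 (295.2 against 429.7 to 451.2), Sele in K2KO library 4 (2485 against 1956 to 2041) and Pi16 in K2KO library 3 (529.4 against 779.8 to 794). Among marker levels, as mean log2, the cardiomyocyte level was 11.09 in K2KO library 2 (others 10.72 to 10.76) and 11.50 in K4KO 2 (10.75 to 10.87), the lymphocyte level 5.11 in K2KO library 2 (4.66 to 4.71), and the mural level 11.38 in control 4 (11.73 to 11.74).

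The interaction test was past the threshold for 6352 genes, so the DKO-labelled libraries differed from the sum of the single changes, with the loss of both genes not shown in them. The log2 interactions of the named ones were 6.79 for Clic6, 5.02 for Tnc, 4.71 for Arg1, 4.60 for Disp2, -4.91 for Myl7, -4.11 for Slc26a10, -3.83 for Cytl1 and -3.80 for Srrm4.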

How the results depend on the processing

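edgeR, DESeq2, the filter of 10, the fits without the 2 Gm10800-rich libraries, the cardiomyocyte covariate and thinning were tests chosen only after the data were seen, and the other alternatives were planned. Where a cause is not named, the cause was not tested. With a 2-fold threshold, which calls fewer genes by construction, the counts were 3488 for DKO against control, 18 for K2KO, 6 for K4KO, 3046 for the interaction, 3324 and 3765 for DKO against K2KO and K4KO, and 40 for K2KO against K4KO. With the cardiomyocyte covariate 1263, 172, 838, 602 and 6 genes were called for DKO against control, the interaction, DKO against K2KO, DKO against K4KO and K4KO, of which 1232, 168, 817, 592 and 6 were also called without it. The K2KO count was 24 without a filter, 63 with only the groups compared, 10 with robust limma, 158 with library weights, 123 with DESeq2 and 18 without the Gm10800-rich libraries. The K4KO count was 8 without a filter, 2 with only the groups compared, 2 with robust limma and 80 with DESeq2. For K2KO against K4KO it was 38 with robust limma, 303 with DESeq2 and 30 without the Gm10800-rich libraries. Leaving out 1 library gave 8185 to 8846 for DKO against control, 13 (K2KO library 2) to 137 (control 3) for K2KO, 4 (controls 1 and 2) to 14 for K4KO, 5361 to 6834 for the interaction, 7629 to 8375 and 8365 to 9692 for DKO against K2KO and K4KO, and 54 (K2KO libraries 3 and 5) to 211 (K4KO 4) for K2KO against K4KO. Of the 9119 DKO calls, 8375 were also called by edgeR (8946 in all) and 8743 by DESeq2 (9227 in all), in the same direction.

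Klf2 in K2KO was -1.06 with an adjusted p of 0.0879 in robust limma, and -1.17 to -0.85 with 1 library left out. Klf2 in the DKO-labelled libraries passed the threshold with the same median (0.63), library weights (0.39), without control 3 (0.57) and without DKO library 2 (0.46), and ranged from 0.25 to 0.57 with 1 library left out. Klf4 there reversed to 0.24 with the same median, 0.14 without control 3, 0.05 without DKO library 2 and 0.06 without DKO library 5, within -0.14 to 0.14 with 1 library left out. Klf4 in K4KO was called with the replicate block (-0.71) and with DESeq2 (-0.74). Over all alternatives the adjusted p ran from 1.08e-06 to 0.0879 for Klf2 in K2KO, 0.00137 to 0.994 for Klf2 in DKO and 0.00377 to 0.396 for Klf4 in K4KO. Klf2 in DKO against K4KO reversed to 0.28 with the same median, 0.05 without K4KO 3 and 0.065 without DKO library 2, within -0.13 to 0.065 with 1 library left out, and Adipoq in DKO against control reversed to 1.02 with the covariate. Called lists went from 16, 12 and 12 in DKO, K2KO and K4KO to 0, 0 and 0 with an estimated correlation, and to 23, 0 and 0 by fry. The overlap of K2KO and K4KO was 0 with split controls and 0 at 2-fold, that of K2KO and DKO 14 at 2-fold, and that of K4KO and DKO 3.33 with split controls and 3 at 2-fold.

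The replicate block for control and K4KO gave 14 called genes, and the calls it changed among the genes and lists named are given beside that comparison. No paired analysis was run for the other comparisons because the K2KO and DKO columns carry numbers that do not match those of the labels, and so no label number. Whether K2KO and DKO columns of the same column number belong together was not tested. Of 3656 values of the 167 genes that the naming rule took for DKO against control over the alternatives, 3538 kept direction and call, 114 lost the call, 3 gained it and 1 reversed. Of these losses 77, and the reversal, came with the cardiomyocyte covariate, where 89 of 167 kept both, and with it 8 of 10 named genes lost the call for the interaction and 6 of 10 each for K4KO and for DKO against K2KO and K4KO. A lost call did not always go with a smaller change. For K4KO the values of Alad (1.01), Tusc1 (1.02), Sele (0.815), Ramp3 (-0.93), Rtn1 (-0.76) and Ankrd33b (-0.66) stayed near those without the covariate. Of 230 values for the 10 K4KO genes 124 kept both and 106 lost the call. Depth limits genes with few reads, such as Clic6 and Arg1. The settings planned for raw counts alone, upper quartile scaling and DESeq2 size factors in edgeR, were not run.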

Other observations

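Single members of further lists were called between the DKO-labelled and control libraries, where neither targeted transcript was lower. None of these lists was called as a whole by camera, and 38.3% of all genes tested were called in this comparison. In the BMP and TGF-beta list 11 of 28 rose and 13 fell (11 and 14 adjusted over the list alone, camera adjusted p = 0.780), with the ligand gene Bmp2 up by 1.82 and the signal transducer genes Smad1 and Smad2 up by 1.01 and 0.83. ADAMTS protease and related genes rose in 8 of 19 cases and fell in 6 (8 and 6 adjusted over the list alone, camera adjusted p = 0.316), with Adamts17 (2.29), Adamts12 (2.10), Adamts2 (1.41) and the proteoglycan gene Vcan (1.79) up. The median of this list was -0.39 while its mean was 0.28, and edgeR on the recovered reads gave a median of 0.45 over 17 members. In the list of the MEKK3, ERK5 and cerebral cavernous malformation pathways, which act upstream of Klf2 and Klf4, 6 of 14 rose and 3 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.746): the receptor gene Heg1 (-0.99) and Ccm2l (-1.24) fell, and Pdcd10 (0.67) and the kinase gene Map3k3 (0.58) rose. Cell cycle arrest and apoptosis genes rose in 9 of 23 cases and fell in 4 (10 and 4 adjusted over the list alone, camera adjusted p = 0.141), with Casp8, an initiator of apoptosis, at 1.03 and the p53 regulator gene Mdm2 at 0.49. In the NF-kB list 5 of 18 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.153), with the inhibitor gene Tnfaip3 at 0.94 and the receptor gene Cd40 at -1.35. Guidance genes rose in 9 of 26 cases and fell in 7 (9 and 7 adjusted over the list alone, camera adjusted p = 0.835), with the repellent ligand gene Sema3a at 1.26 and the ephrin receptor gene Epha4 at -1.32. With libraries scaled to the same median the numbers higher and lower were 13 and 1 for the NF-kB, 14 and 2 for the arrest and apoptosis, 12 and 4 for the guidance, 12 and 12 for the BMP and TGF-beta, 8 and 3 for the ADAMTS and 7 and 2 for the MEKK3 list.

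Endothelial subtype markers were mixed as well. Venous genes rose in 3 of 14 cases and fell in 6 (3 and 6 adjusted over the list alone, camera adjusted p = 0.387), with Tmsb10 at 2.03, Nrp2 at 0.66 and the venous regulator gene Nr2f2 at -0.45. Cardiac capillary genes rose in 5 of 17 and fell in 5 (5 and 6 adjusted over the list alone, camera adjusted p = 0.656), with the glycerol channel gene Aqp7 at -1.32, the transcription factor gene Tcf15 at -0.87 and the fatty acid binding gene Fabp5 at 1.20. Lymphatic genes rose in 4 of 9 and fell in 3 (4 and 3 adjusted over the list alone, camera adjusted p = 0.975), with Nts at 2.32 and the lymphatic regulator gene Prox1 at -0.72. Endocardial genes rose in 1 of 13 and fell in 3 (1 and 3 adjusted over the list alone, camera adjusted p = 0.313), with Tgfbi at 1.46. Scaled to the same median, the venous list had 3 higher and 2 lower, the cardiac capillary list 6 and 4, the lymphatic list 5 and 3 and the endocardial list 2 and 1. Among other cells, neutrophil genes fell in 5 of 15 cases (5 adjusted over the list alone, camera adjusted p = 0.141), with the lactoferrin gene Ltf at -1.76. Schwann cell genes fell in 4 of 8 and rose in 1 (4 and 2 adjusted over the list alone, camera adjusted p = 0.109), with Sox10 at -1.83, and mesothelial genes fell in 4 of 11 and rose in 1 (4 and 1 adjusted over the list alone, camera adjusted p = 0.313), with Msln at -2.48 and Wt1 at 0.94. Platelet genes rose in 3 of 14 and fell in 2 (3 and 2 adjusted over the list alone, camera adjusted p = 0.978), with the integrin gene Itgb3 at 2.63 and Gp9 at -1.47. Of 6 adipocyte genes 1 fell (1 adjusted over the list alone, camera adjusted p = 0.367), Plin4 at -1.78. In the sex-linked list 2 of 6 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.978), with the Y-linked Ddx3y at 7370 ± 313 against 5363 ± 294, and Xist, of the inactive X chromosome, at 1.04 ± 0.763 against 4.92 ± 0.987. Median and mean differed in sign for the fibroblast (0.11 and -0.02), endothelial identity (0.04 and -0.01) and guidance (-0.02 and 0.02) lists. For the platelet and sex-linked lists both were negative while camera pointed up. Some genes sit in more than 1 list: Acta2, Cnn1 and Tagln in the matrix and mural lists, Col1a1, Col1a2, Col3a1 and Postn in the matrix and fibroblast lists, and Itgb3 in the matrix and platelet lists.

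Values per library are given here for a few genes chosen after their values were seen. Gm7809 stood at 19.8, 14.5, 14.5 and 19.0 scaled counts in controls 1 to 4, at 13.1, 16.1, 173.8 and 139.3 in K4KO 1 to 4, at 743.8, 571.4, 681.4 and 721.1 in K2KO libraries 2 to 5 and at 1378, 1613, 1696 and 1537 in DKO libraries 2 to 5. Calr3 stood at 18.9, 17.5, 25 and 45.6 in K4KO 1 to 4, and Mri1 at 260.8, 244.4, 179.8 and 167.1. Ankrd6 stood at 307.4, 304.8, 295.3 and 273.5 in K4KO 1 to 4, and between 86.4 and 131.5 in the other 12 libraries.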
